A study of Arabidopsis thaliana with 4 samples.

How the data were processed

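Transcript levels were measured in above-ground tissue of Arabidopsis thaliana with Affymetrix arrays, with 4 arrays in all. The samples were an fnr1 mutant and a wild type plant line in each of 2 ecotypes, Columbia and Wassilewskija (Ws), with 1 array for each of the 4 combinations. Per the labels' protocols, plants were grown on soil at pH 6.5 and 21 °C, with 8 h of light at about 100 µmol photons per square metre per second and 16 h of dark. Tissue was taken at 31 days of age, 4 h into the light period, and biotin-labelled cRNA was made from 3 µg of total RNA. The deposited values are linear intensity signals, 1 per probe set and array, made with MAS5 per the submitters' processing notes. The MAS5 version, its scaling target and its detection calls were not given in the sources used here.

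The arrays were not at a common level as deposited. The mean signal after trimming 2% of probe sets at each end was 84.0 for fnr1 Columbia, 89.5 for wild type Ws, 81.5 for fnr1 Ws and 68.1 for wild type Columbia. The design, fixed before the data were examined, assumed a common MAS5 scale and kept the deposited scale, so that scale was used for the tests and results after median scaling of the arrays are printed where they differ.

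From the deposited intensity values, log2(signal + pseudocount) was computed with a pseudocount of 5.73, the 25th percentile of all signals. Log2 differences therefore understate the change of dim probe sets. Where a gene named for a tested comparison had a signal below 5.73 in its dimmer group, its size was given as a lower bound on the fold, from mean log2 signals with each lower signal set to 5.73. The 64 control probe sets were left out of the 22810, and the 13648 of the 22746 others with a mean log2 signal at or above the 40th percentile were tested. Differences were tested with limma 3.58.1 in R 4.3.3, with ecotype and genotype as additive terms, a trend of the variance on mean signal, 2-sided tests and Benjamini-Hochberg adjustment at 0.05. This model leaves 1 residual degree of freedom, so the ecotypes are the replicates of the genotype comparison and the genotypes those of the ecotype comparison. The estimated prior degrees of freedom were infinite on the deposited scale. The spread of each probe set was thus set by the trend alone, and its own disagreement between the pairs entered neither its SE nor its p. After median scaling the prior degrees of freedom were 15.2. Nothing in the labels says how many plants or cultures each array stands for, and p-values measure only the spread between these arrays. The number of arrays limits the precision. Differences within 1 ecotype or 1 genotype, and the genotype by ecotype difference, had no replicates and were not tested.

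The probe annotation listed 14016 probe sets, 13513 with 1 gene and 503 with several, and 8730 non-control probe sets were not listed. Of those with 1 gene, 13436 matched the TAIR10.1 gene table by gene ID and 77 kept the annotation's symbol. Among the tested probe sets, 7353 had 1 gene, 274 had several and 6021 were not listed, and genes were named only from the first kind. FNR1 and FNR2 were not analysed here, because no probe set was listed for them.

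Genes were named by a rule fixed before the data were examined. For each of the 2 comparisons it took the 12 highest and 12 lowest genes among those called and at least 1.5-fold apart the same way in both pairs of arrays. Open places in the genotype comparison were filled by the genes with the largest smaller-of-the-pair difference, which were not called. It also took the 4 highest and 4 lowest genes in each ecotype that were under 1.5-fold apart in the other, the 4 highest and 4 lowest by genotype by ecotype difference, and from each gene list the members with the smallest p and any called member. Other probe sets named were chosen after their values were seen.

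Of 20 gene lists fixed before the data were examined, 52 of 335 entries had a probe set listed and 43 were tested, which left 9 lists with at least 3 tested members. A further 20 lists with 335 entries were built from the probe annotation, after it was read and before any expression difference was examined; 333 entries had a probe set, 207 were tested and 19 lists had at least 3. Each gene was represented by its probe set with the highest mean signal. Lists were tested with camera in limma at a preset correlation of 0.01, adjusted within each family of lists, and again with an estimated correlation and on ranks. The estimated correlation rests on 1 residual degree of freedom. With it no list was called in either comparison and the lowest camera adjusted p was 0.906, so it cannot decide about any list. List medians are given relative to the median of all tested probe sets, with their percentile among 10000 random lists of the same size matched on mean signal.

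The procedure was tested on simulated data over 13648 probe sets with 50 changed probe sets per size. Noise was independent and normal, with the SD of the variance trend after median scaling, and each change was the same in both pairs. The model's assumptions thus held by construction, and the counts do not give the error rate on the real arrays. For the genotype comparison the procedure recovered 20 of 50 at a log2 change of 1, 48 at 1.5 and 50 at 2 and at 3. For the ecotype comparison it recovered 24, 48, 50 and 50. It called 0 unchanged probe sets on the deposited scale. After median scaling it recovered 44, 49, 50 and 50 for the genotype and 45, 50, 50 and 50 for the ecotype comparison, and called 5 and 10 unchanged probe sets. Alternatives fixed beforehand were no pseudocount or one at the 50th percentile, no filter or one at the 60th percentile, median scaling, quantile and cyclic loess normalization, no variance trend, and the other factor left out of the model. Leaving out each array in turn was added after seeing the data; the other factor was then dropped from the model, because the additive model on 3 arrays leaves no residual degree of freedom.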

Results

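The series set the effect of a mutation in FNR1 against the variation between ecotypes. FNR1 is a leaf ferredoxin-NADP+ oxidoreductase, the chloroplast enzyme that passes electrons from ferredoxin, reduced by photosystem I, to NADP+. Columbia and Wassilewskija (Ws) are natural accessions of Arabidopsis thaliana, and each was measured as an fnr1 mutant and as wild type, with 1 array for each of the 4 combinations. The wild type Columbia array was dimmer than the others, with a median signal of 22.1 against 27.5 to 28.9. Its median signal over 69 plastid probe sets was 1040, against 1500 in fnr1 Columbia, 1565 in wild type Ws and 1442 in fnr1 Ws. The ratio of 3' to 5' signal of the actin control was 2.36 to 2.78 over the 4 arrays, and that of the GAPDH control was 0.76 to 0.90. An older actin control on the same arrays was less even, at 30.3 in fnr1 Columbia, 20.3 in wild type Ws, 18.8 in fnr1 Ws and 15.2 in wild type Columbia, while the older GAPDH control had 1.32 to 1.48. Arrays of the same ecotype correlated most closely across probe sets, with r = 0.976 for the Columbia pair and 0.982 for the Ws pair, against 0.946 to 0.952 across ecotypes. FNR1 was not analysed here, so the mutant labels were taken as given.

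The first comparison asked which transcripts differed between fnr1 and wild type plants over both ecotypes. A small set of transcripts rose in the mutant, and 1 probe set fell. AT3G60420, a phosphoglycerate mutase family gene, rose by a fitted log2 difference of 1.91 ± 0.31 (SE from the variance trend, 2 arrays against 2, limma adjusted p = 1.22e-06, and 0.00444 after median scaling). Its log2 difference was 2.61 in Columbia and 1.22 in Ws, a disagreement that does not enter this SE. AT1G19960 rose by 1.82 ± 0.32 (limma adjusted p = 2.71e-05, and 0.000167 after median scaling). AT5G55450, a lipid transfer protein family gene, rose by 1.65 ± 0.31 (limma adjusted p = 0.000165, and 0.000877 after median scaling). The probe set that fell has no gene in the annotation used. It had a signal of 1501 and 1626 in wild type Columbia and Ws against 100.0 and 2.07 in the mutants. Its limma adjusted p was 3e-63 as deposited, where its own disagreement between the ecotypes does not enter, and 6.85e-06 after median scaling. The signal of 2.07 lies below the pseudocount of 5.73 that was added before taking logs, so no size is given over both ecotypes. The log2 difference in Columbia was -3.83.

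In all, limma called 29 of 13648 probe sets, 28 higher and 1 lower in fnr1, and 9 of them had a single named gene. Differences were at least 1.5-fold the same way in both ecotypes for 23 of the 29. AT5G52750 (1.45, adjusted p = 0.00635), AT4G38550 (1.34, adjusted p = 0.0161), the cytochrome P450 gene CYP71B23 (1.27, adjusted p = 0.036) and AT1G64360 (1.2, adjusted p = 0.0393) also rose, each at least 1.5-fold in both ecotypes. The other 2 named genes were called with a small difference in Ws. AT5G03350, a legume lectin family gene, was fitted at 1.32 (adjusted p = 0.0278) with 2.37 in Columbia and 0.27 in Ws. AT1G11330, a lectin-type receptor kinase gene, was fitted at 1.27 (adjusted p = 0.019) with 2.05 in Columbia and 0.50 in Ws. The highest probe set without a named gene rose by 2.79 ± 0.31 (limma adjusted p = 9.43e-16, and 0.000167 after median scaling).

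**Figure D1:**
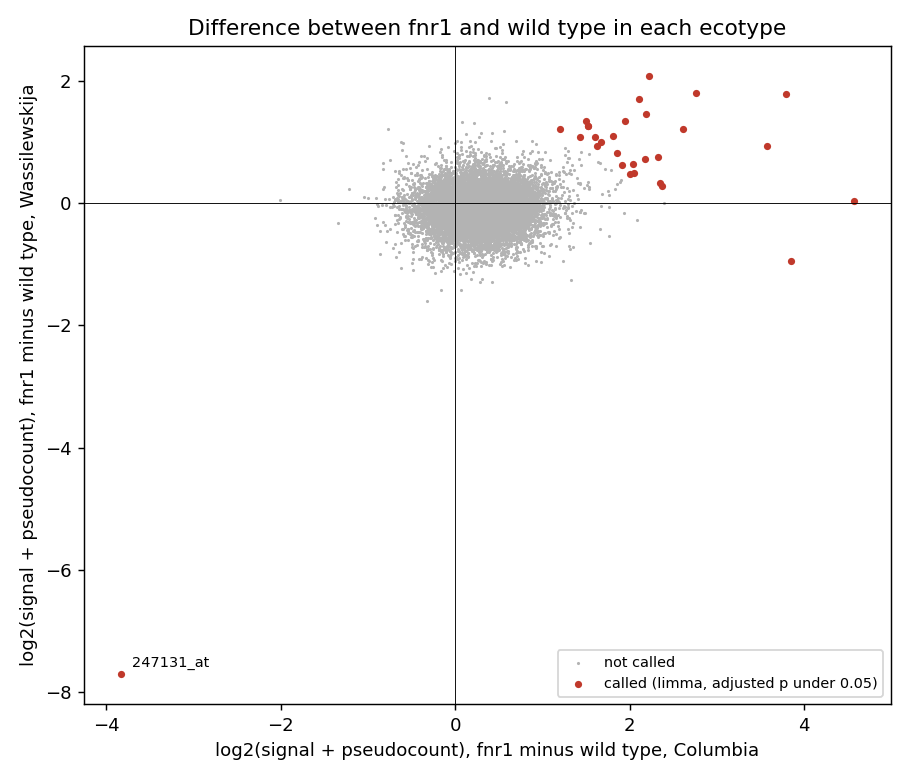
Log2 difference between fnr1 and wild type in Columbia (horizontal axis) and in Ws (vertical axis), 1 point per tested probe set, with the 29 probe sets called by limma in red. The called points lie at the right of 0 except the probe set that fell, at -3.83 in Columbia and -7.71 in Ws, the latter set by the pseudocount.

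**Figure D2:**
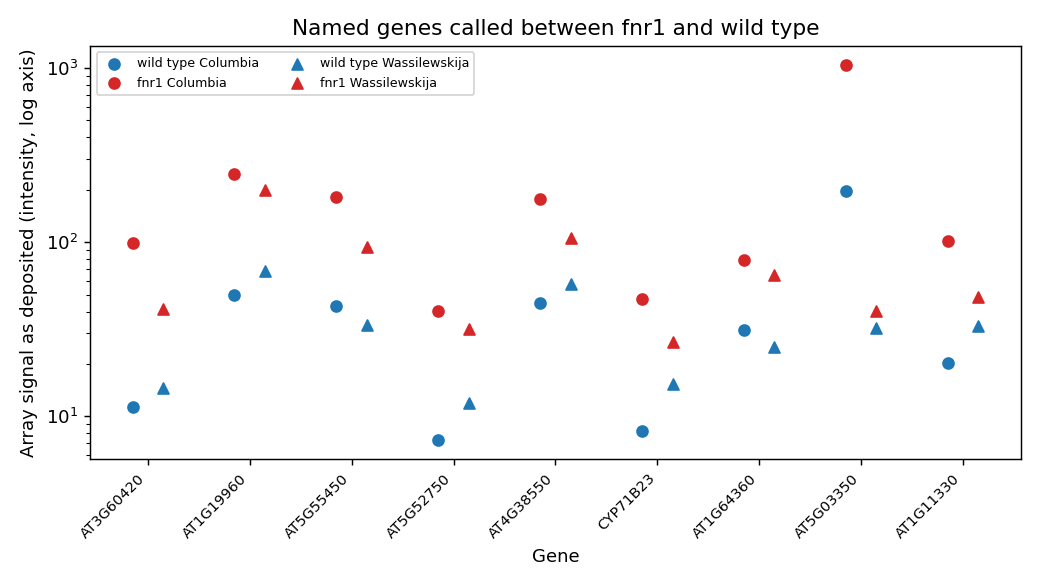
Deposited signal (log axis) of the 9 named genes called between fnr1 and wild type, 1 point per array, with Columbia as circles, Ws as triangles, wild type in blue and fnr1 in red. The fnr1 point lies above the wild type point of the same ecotype for each gene, with the smallest gap for AT5G03350 in Ws, at 40.3 against 32.3. For the 7 genes at least 1.5-fold higher in both ecotypes, the naming rule required the fnr1 point to lie above.

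Several named genes were similar in size in both ecotypes without passing the test, which is what the rule for open places picked them for. Higher values in fnr1 were seen for AT5G43440 (0.94, limma adjusted p = 0.559), AT5G25800 (0.89, adjusted p = 0.901), AT5G35735 (0.78), AT1G76510 (0.78) and AT5G11610 (0.77), the last 3 with an adjusted p of 1. None of the 12 lower genes of the naming rule was called. AT4G34950 had the lowest value (-0.85, adjusted p = 1), with -0.87 in Columbia and -0.83 in Ws. AT4G31050 (-0.79), AT3G54290 (-0.68), AT1G14300 (-0.61), AT3G26960 (-0.58), AT2G41200 (-0.57), AT5G10320 (-0.56), AT1G15170 (-0.56), AT5G01020 (-0.53), AT1G63100 (-0.52), AT2G47350 (-0.51) and IMP4 (-0.51) also had an adjusted p of 1.

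Of 20 gene lists fixed before the data were examined, 9 had enough measured members to test. With camera in limma, 0 of these 9 and 0 of 19 added lists were called between fnr1 and wild type, with 1 and 2 at an unadjusted p under 0.05. Other settings gave 2 calls: the rapid stress and wounding response list was called higher in fnr1 with no filter (adjusted p = 0.00505), where 3 of its members were tested, and the cold and drought response list was called higher with quantile normalization (adjusted p = 0.0412). None of the 35 measured members of the first lists was called over all genes, and 1 was called higher when adjusted over the list alone. As deposited, the lowest adjusted p was that of the cold and drought response genes COR15A, COR15B, COR47 and LTI30 (median 0.20 above all probe sets, camera adjusted p = 0.135). With an estimated correlation it was 0.973, in a check that cannot decide about any list. The medians of the 3 LHCB4 antenna genes (-0.01, with a mean of 0.02), of 5 photosystem and electron carrier genes (-0.08), of 3 cyclic electron flow genes (-0.05, with a mean of 0.01), of 3 Calvin-Benson cycle genes (-0.06) and of 6 antioxidant enzymes (-0.10) lay near that of all probe sets. Those of 5 chlorophyll and heme synthesis genes (-0.16), 3 anthocyanin and flavonol synthesis genes (-0.07, with a mean of 0.06) and 3 glucosinolate genes (0.04, with a mean of -0.02) were not called either. In these 4 lists with a mean of the other sign, camera's direction followed the mean. Among the added lists, none of 206 measured members was called, and medians ran from -0.07 to 0.18, with median, mean and camera differing in sign for 5 of the 19 lists.

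The log2 values include a median shift of all probe sets of 0.08, which was -0.02 after median scaling. Median scaling called 24 probe sets, 19 of them shared, and the calls of CYP71B23 (adjusted p = 0.217), AT5G03350 (0.17), AT1G11330 (0.121) and AT5G52750 (0.0504) ended. With 3 arrays the additive model has no residual degree of freedom, so leaving out an array also dropped ecotype from the model, a change that on its own gave 11 calls. Limma then called 0 probe sets without wild type Columbia or without wild type Ws (255 and 1018 at an unadjusted p under 0.05). Without fnr1 Columbia it called 9, of which 8 were lower in fnr1 and 1 was among the 29, and without fnr1 Ws it called 25, of which 12 were among them. Of the 7 named genes at least 1.5-fold higher in both ecotypes, AT3G60420 was called without fnr1 Ws (adjusted p = 0.00519), and no other was called with an array left out, although each stayed higher in fnr1.

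Within a single ecotype the differences had no replicate check and were not tested. After median scaling, 104 probe sets were at least 2-fold higher and 29 lower in fnr1 in Columbia, against 38 higher and 19 lower in Ws. On the deposited scale, which carries the dim wild type Columbia array, these counts were 284 and 5 in Columbia and 31 and 37 in Ws. The gene values that follow are on the deposited scale, where the median over all probe sets was 0.28 in Columbia and -0.11 in Ws. After median scaling, for example, AT5G03350 had 2.11 and AT3G28670 had -2.28 in Columbia. In Columbia and under 1.5-fold apart in Ws, the highest named genes in fnr1 were AT5G03350 (2.37), AT3G22240 (2.09), AT1G11330 (2.05) and AT5G59670 (1.89), and the lowest were AT3G28670 (-2.01), CR4 (-1.34), AT4G37220 (-1.21, with an fnr1 signal of 5.35 that lies below the pseudocount) and AT1G09290 (-1.0). In Ws and under 1.5-fold apart in Columbia, the highest were AT4G18400 (1.15), AT5G07950 (1.14), AT3G29130 (1.12) and the sugar transporter gene SWEET13 (1.08). The lowest there were AT1G67210 (-1.61), AT2G22100 (-1.42), AT5G30490 (-1.30) and AT1G66760 (-1.24).

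The genotype differences of the 2 ecotypes, which share no array, were weakly related across probe sets (Pearson's r = 0.107, Spearman's rho = 0.048). Probe sets are not independent replicates, so no p is given. On the deposited scale 15 probe sets were at least 2-fold higher in fnr1 in both ecotypes, where 0.645 would be shared by independent lists, and after median scaling 14, where 0.29 would be. The probe set that fell in fnr1 was the 1 that was at least 2-fold lower in both.

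The second comparison asked which transcripts differed between the ecotypes over both genotypes. The signal of a thionin family gene, AT1G66100, was far lower in Ws, at 1331 and 1533 in Columbia wild type and fnr1 against 3.45 and 0.31 in Ws. Both Ws signals lie below the pseudocount of 5.73, so the size of the difference is given as a bound. With such signals set to 5.73, AT1G66100 was at least 249-fold lower by the mean of log2 signals (limma adjusted p = 1.82e-118, and 5.8e-14 after median scaling). ECS1 fell by 7.54 ± 0.33 on the log2 scale (SE from the variance trend, 2 arrays against 2, limma adjusted p = 5.33e-110, and 1.76e-14 after median scaling). Among the genes higher in Ws, AT1G50290 rose by 3.72 ± 0.32 (adjusted p = 7.45e-29) and AT2G15560 by 3.47 ± 0.31 (adjusted p = 8.09e-27). AT5G15360, with Columbia signals of 1.58 and 4.22, was at least 19.8-fold higher on the same bound (adjusted p = 6.59e-31). For the genes lower in Ws, here and below, the folds are those of array signals. Base differences under probes designed on Columbia, or a gene missing from Ws, could also lower a Ws signal, and this was not tested for single genes.

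In all, limma called 449 probe sets, 207 higher and 242 lower in Ws, and 223 of them had a single named gene. Differences were at least 1.5-fold the same way in both genotypes for 421. Other named genes that fell in Ws were AT3G22240 (-6.40), AT1G73490 (-4.14), AT5G03350 (-3.46) and ZW9 (-3.22). A further 6 fell to a Ws signal below the pseudocount on at least 1 array, so that only the same bound holds. AT2G32160 was at least 43-fold lower, AT3G47250 38.4-fold, AT3G44630, a disease resistance gene of the TIR-NBS-LRR class, 19.5-fold, AT1G65370 16.5-fold, AT3G43740 14.2-fold and AT4G02540 12-fold. The highest limma adjusted p among these 10 genes was 4.81e-20 as deposited and 2.99e-06 after median scaling. AT5G22430 rose in Ws by at least 10.3-fold, with 1 Columbia signal below the pseudocount. Other named genes that rose in Ws were AT5G55570 (2.52), AT1G20490 (2.27), AT2G35820 (2.25) and AT2G20870 (2.08). ACLA-2, a subunit of ATP-citrate lyase (2.02), AT3G59780 (1.87), the glycosyltransferase gene UGT87A2 (1.82) and AT1G48750 (1.69) rose too, with a highest limma adjusted p of 3.44e-05.

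**Figure D3:**
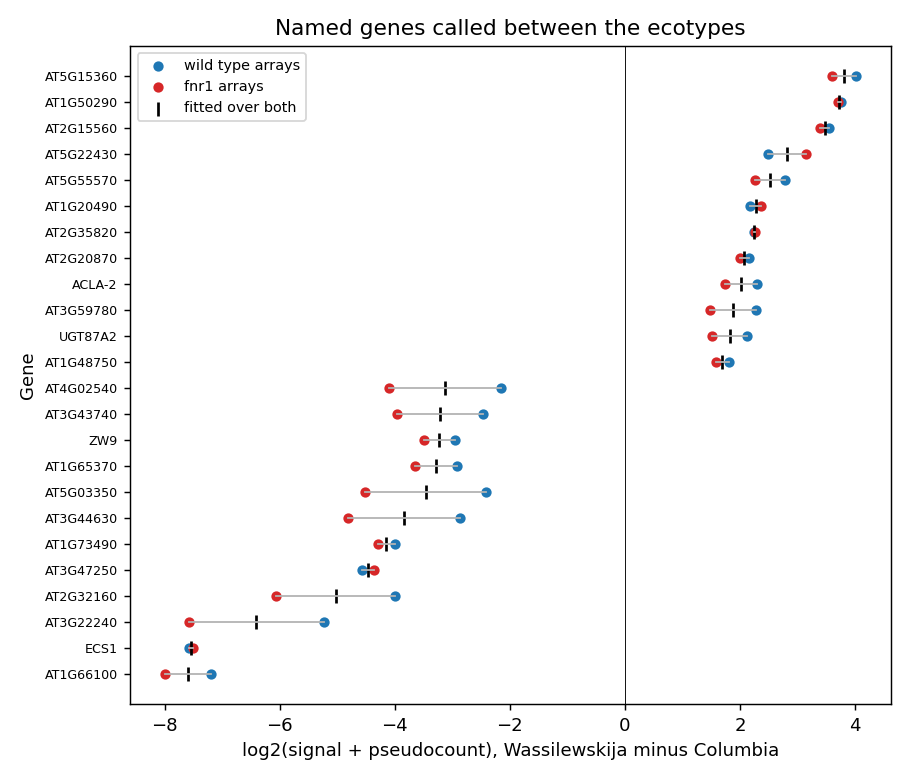
Difference in log2(signal + 5.73) between Ws and Columbia (horizontal axis) of the 24 named genes of the ecotype comparison, in the wild type arrays (blue), in the fnr1 arrays (red) and as fitted over both (black mark). The wild type and fnr1 points lie on the same side of 0 for each gene, which the naming rule required. They run from -7.19 and -7.99 for AT1G66100 to 4.01 and 3.60 for AT5G15360. Both of these genes had signals below the pseudocount in the dimmer ecotype, which sets how far out they lie.

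One gene list was called between the ecotypes. The light-harvesting complex list, of which 3 genes of the minor antenna protein LHCB4 were measured, was lower in Ws (median -1.06 relative to all probe sets, camera in limma, adjusted p = 0.0257). That call was lost on ranks (adjusted p = 0.236). With an estimated correlation its camera adjusted p was 0.99, but that check rests on 1 residual degree of freedom, called no list and decides nothing here. LHCB4.2 fell by 0.91 ± 0.24 on the log2 scale (limma adjusted p = 0.00933), while LHCB4.3 had -0.85 (adjusted p = 0.169) and LHCB4.1 had 0.11 (adjusted p = 0.869). As deposited, 1 member was called over all genes and 2 when adjusted over the list alone. After median scaling LHCB4.3 was called over all genes too (-1.01, limma adjusted p = 0.00158). The camera adjusted p of the list was then 0.00357. Of the 6 antioxidant enzymes, CCS, the copper chaperone of superoxide dismutase, rose by 1.46 ± 0.33 in Ws (adjusted p = 0.000718), and the list was not called (median -0.00, mean 0.21 and a positive camera direction, adjusted p = 0.796). The jasmonate response list had under 3 measured members, of which the defensin genes PDF1.2A (1.5, limma adjusted p = 9.3e-05) and PDF1.2B (1.33, limma adjusted p = 0.00185) rose. Whether their 2 probe sets measure the 2 genes separately was not tested. As deposited, the cold and drought response list had no member called over all genes and 1 called higher when adjusted over the list alone (median 0.12, camera adjusted p = 0.796). After median scaling its member COR15B was called higher over all genes (0.79, limma adjusted p = 0.0251). No member was called as deposited in the lists of photosystems and electron carriers (-0.03, with a positive camera direction), cyclic electron flow (-0.09, with a mean of 0.05 and a positive camera direction) and Calvin-Benson cycle (-0.07, with a positive camera direction). The same held for chlorophyll and heme synthesis (-0.18), anthocyanin and flavonol synthesis (-0.65, camera adjusted p = 0.375) and glucosinolates (0.01). After median scaling GSA1, of chlorophyll and heme synthesis, was called lower (-0.61, limma adjusted p = 0.0255).

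The log2 values include a median shift of all probe sets of 0.21, which was 0.06 after median scaling, and median scaling called 1024 probe sets, 401 higher and 623 lower, with 439 of the 449 among them, while cyclic loess called 353 higher and 773 lower (68.7% lower against 53.9%). The balance turned the other way with genotype left out of the model, at 473 higher and 345 lower (42.2% lower), and with no variance trend, at 303 and 282 (48.2% lower). Leaving out an array also dropped genotype from the model. Without fnr1 Columbia, the dim wild type array was the only Columbia array. The median log2 difference of all probe sets was then 0.34, against 0.07 without wild type Columbia, 0.27 without fnr1 Ws and 0.16 without wild type Ws. The counts that follow include this shift, and its part in them was not tested. Without fnr1 Columbia 2437 were called, 2133 higher and 304 lower (12.5% lower), whereas the calls were 361 higher and 549 lower without wild type Columbia, 81 and 143 without fnr1 Ws, and 63 and 151 without wild type Ws. Each of the 24 named genes was called in all 4 of these fits, with the same sign.

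The ecotype differences in wild type and in fnr1, which share no array, were related across probe sets (Pearson's r = 0.617, Spearman's rho = 0.388, with no p since probe sets are not independent replicates). Of the tested probe sets, 88 were at least 2-fold higher in Ws in both genotypes, where 8.53 would be shared by independent lists, and 160 were lower, where 5.62 would be. After median scaling the counts were 61 and 228, where 2.25 and 10.6 would be.

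The 4 arrays can be split 2 against 2 by genotype, by ecotype or by the genotype by ecotype difference, and the SD over probe sets of these contrasts was 0.245, 0.452 and 0.220. At least 2-fold from the median of the contrast, 39 probe sets were higher and 3 lower by genotype, 92 higher and 349 lower by ecotype, and 2 higher and 6 lower by the genotype by ecotype difference. These spreads were described and not tested. The genes with the highest difference between the fnr1 effect in Ws and in Columbia were AT3G28670 (2.05), AT2G39960 (1.97), AT1G52180 (1.61) and AT2G31010 (1.58). Those with the lowest were AT3G22240 (-2.36), AT1G16670 (-2.21), AT5G03350 (-2.10) and AT2G32160 (-2.08). For AT2G32160 this is not a measured gap, because both Ws signals lie below the pseudocount. The Ws signals of AT3G22240 were low too, at 16.3 and 12.5.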

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

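The differences in this part were not tested, because each ecotype had 1 array per genotype. They are listed because the difference between fnr1 and wild type had opposite signs in the 2 ecotypes, both as deposited and after median scaling. Values are as deposited. AT3G22240 was higher in fnr1 in Columbia by 2.09 and had a log2 difference of -0.27 in Ws, a gap of -2.36. Its signals in wild type and fnr1 were 16.3 and 12.5 in Ws, below the array medians of 28.9 and 27.5, against 816 and 3487 in Columbia. A missing gene or base differences under the probes could lower a Ws signal and were not tested. These values therefore do not show whether the gene responded to the mutation in Ws. AT1G16670 had 1.55 in Columbia and -0.66 in Ws, a gap of -2.21. AT2G32160 had 1.36 and -0.72, a gap of -2.08, but its Ws signals of 4.23 and 0.31 lie below the pseudocount of 5.73, so neither its direction in Ws nor the gap is a measured value. AT3G28670 had -2.01 in Columbia and 0.04 in Ws, a gap of 2.05. Its Ws signals of 32.3 and 33.4 hardly differed, so the gap lies in Columbia and is not an opposite response. AT2G39960 had -0.77 and 1.2, a gap of 1.97. AT1G52180 had -0.62 and 0.99, a gap of 1.61, and AT2G31010 had -0.59 and 0.98, a gap of 1.58. A probe set with no named gene, chosen after its values were seen, was called by limma over both ecotypes although it had 3.85 in Columbia and -0.95 in Ws, a gap of -4.80.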

How the results depend on the processing

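Leaving out arrays, and the alternatives of the added gene lists, were chosen after seeing the data; the other alternatives were fixed before. The count of probe sets called between fnr1 and wild type was 29 and became 15 with the stricter filter, where fewer were tested, and 11 with no replicate block, that is without ecotype in the model. Without 1 array it ran from 0 to 25; these fits also leave out the other factor, so that the ecotype difference enters the residual and the estimate, and assume that the lone array of a group varies like the others. Of the 25 calls without fnr1 Ws 12 were among the 29, and of the 9 without fnr1 Columbia 1 was. The other alternatives fixed before gave 23 to 39. The ecotype count of 449 became 252 with the stricter filter, 1024 with median scaling, 1227 with quantile normalization, 1126 with cyclic loess and 818 with no replicate block, and ran from 214 to 2437 without 1 array. The 3 scalings remove a shift common to all probe sets of an array, which the model otherwise counts partly as residual and partly as a difference. With median scaling the genotype count went down, to 24. The cause of the changed counts was not tested for any setting. Of the 9 of 20 planned gene lists that could be tested, 0 were called for genotype (1 at an unadjusted p under 0.05), but 1 was with no filter (rapid stress and wounding response, adjusted p = 0.00505, with 3 members only then tested) and 1 with quantile normalization (cold and drought response, adjusted p = 0.0412). The 1 list called for ecotype became 0 with no filter and 0 with rank-based camera. The count was also 0 with an estimated correlation, which called no list in either comparison and decides nothing here. Of the added lists, 0 were called for ecotype, but 1 was with no filter (flavonoid enzymes), 1 each with median scaling, quantile normalization, cyclic loess and no replicate block (plastid-encoded gene expression machinery), and 2 with rank-based camera (the plastid list, adjusted p = 0.0158, and flavonoid enzymes, adjusted p = 0.0498); the causes were not tested. The correlation of the genotype differences, 0.107, was 0.0052 with no filter and 0.155 with the stricter filter. That of the ecotype differences, 0.617, was 0.628 with the pseudocount at the 50th percentile, 0.379 with no filter and 0.664 with the stricter filter. Signal over background was not measured here. The SD of the disagreement between the ecotypes' genotype differences was 0.719, 0.849, 0.534, 0.408 and 0.35 over 5 equal groups of all probe sets from dim to bright, and 2.92, 2.0, 0.687, 0.445 and 0.365 without the pseudocount, which holds the values of dim probe sets down, while the correlation of the genotype differences went from -0.03 in the dimmest to 0.21 in the brightest group and that of the ecotype differences from 0.05 to 0.71. With all 4 arrays kept, of 218 recomputed values of the 26 genes named for genotype, none changed sign, 18 lost a call and 2, both of AT4G34950 (lower, adjusted p = 0.0127 with quantile normalization and 0.0419 with cyclic loess), gained one; AT3G60420, AT1G19960 and AT5G55450 were called under each of these alternatives that tested them, but with an array left out AT3G60420 was called only without fnr1 Ws and the other two never. Of 300 such values of 35 ecotype genes, none changed sign and 5 lost a call, all with no filter. Within 1 ecotype or 1 genotype, 82 values of these 26 and 35 genes lay within 1 standard error of the fitted value and 40 further away, none with the opposite sign. Most of these genes were named because both pairs went the same way, so the lack of opposite signs was largely fixed beforehand. Of 498 recomputed medians of gene lists, 448 kept their direction and their side of the threshold, 6 gained a call, 1 lost it and 43 changed sign, none of these 43 called before or after; the cause was not tested. For genotype, these were 0.0046 for small heat shock genes with no pseudocount. With the pseudocount at the 50th percentile they were 0.0163 (light-harvesting), 0.0129 (plastid cytochrome b6f and ATP synthase) and 0.0034 (glycosyltransferases). With no filter they were 0.021 (light-harvesting), -0.0616 (glucosinolates), 0.0181 (plastid cytochrome b6f and ATP synthase), 0.0083 (plastid gene expression), 0.03 (flavonoid), -0.0818 (glutathione transferases) and -0.091 (expansins). With the stricter filter they were 0.0187 (plastid cytochrome b6f and ATP synthase), 0.1384 (mitochondria-encoded), 0.0784 (flavonoid), 0.0357 (glycosyltransferases), 4e-04 (defensins) and 0.0267 (small heat shock). With quantile normalization they were 0.0272 (light-harvesting), 0.0294 (plastid cytochrome b6f and ATP synthase) and 0.0234 (plastid gene expression), and with cyclic loess 0.0645, 0.0381 and 0.0157 for the same lists and 0.0041 for the Calvin-Benson cycle. For ecotype, with the pseudocount at the 50th percentile they were 0.0195 (photosystems), 0.0414 (antioxidant), 0.0157 (nuclear photosynthesis) and -0.0241 (cold and dehydration). With no filter they were 0.0186 (photosystems), 0.0478 (antioxidant), -0.0103 (mitochondria-encoded), 0.0148 (nuclear photosynthesis) and -0.1502 (defensins). With the stricter filter they were 0.0113 (expansins), -0.3012 (cold and dehydration) and -0.0679 (autophagy). With quantile normalization they were 0.0082 (photosystems), 0.0296 (antioxidant), -0.0065 (glucosinolates) and 0.0011 (nuclear photosynthesis), and with cyclic loess 0.0132 (photosystems), 0.0014 (antioxidant) and -0.0015 (glucosinolates).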

Other observations

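Tests on the dim wild type Columbia array as a source of the Ws pattern, on sequence differences and on array noise, and the counts with median scaling and cyclic loess, were chosen after the result was seen; the other tests were fixed before. Beyond the genes above, members of the added lists differed between the ecotypes, although camera in limma at the preset correlation called none of the 19 lists (3 at an unadjusted p under 0.05) and called 2 on ranks. Of 206 measured members, 6 were called higher and 4 lower in Ws. Plastid-encoded psbA, which encodes the D1 protein of photosystem II, rose by 1.03 ± 0.28 (SE from the variance trend, 2 arrays against 2, limma adjusted p = 0.00923). The cytochrome b6f subunit gene petG rose by 1.22 (limma adjusted p = 0.00916) and the ribosomal protein gene rps4 by 1.14 (limma adjusted p = 0.000396). The median of 20 plastid genes for transcription and translation was 0.24 above all probe sets (camera adjusted p = 0.153, and adjusted p = 0.0158 on ranks). The adjusted p of 0.906 with an estimated correlation decides nothing here. That median lay at the 99.99th percentile of random lists in wild type and the 99.32th in fnr1. The list was also called by camera after median scaling (adjusted p = 0.0169), quantile normalization (adjusted p = 0.00882) and cyclic loess (adjusted p = 0.00573). Other plastid-encoded lists went both ways, and none of them was called. The medians of photosystem I (0.23) and photosystem II (0.14, with 0.26 in wild type and -0.065 in fnr1) lay above all probe sets. Those of the NDH complex (-0.13) and of cytochrome b6f and ATP synthase (-0.08, with a mean of 0.10), which holds petG, lay below. Plastid probe sets were also dimmest on the wild type Columbia array, at a median signal of 1040. Of 5 defensin and thionin genes, the 2 that were called are the PDF1.2 pair already named. Of 17 tubulin, histone and mitosis genes, the histone gene HTB11 fell by 2.95 ± 0.31 on the log2 scale (adjusted p = 1.27e-18). The expansin gene EXPA8 rose by 1.04 (adjusted p = 0.0337), UGT85A2 fell by 1.17 (adjusted p = 0.0106) and AT1G54050, of the small heat shock list, fell by 1.13 (adjusted p = 0.0181), all with limma. The median of 5 flavonoid genes was -0.65 (camera adjusted p = 0.153, and adjusted p = 0.0498 on ranks), with no member called. Its adjusted p of 0.906 with an estimated correlation decides nothing either.

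More probe sets were strongly lower than strongly higher in Ws, at 349 against 92 that were 2-fold or more from the median. The dim wild type Columbia array is argued against as the whole source, because the 2 fnr1 arrays, which leave it out, still had 419 lower and 139 higher, or 75.1% lower, against 73.4% in the 2 wild type arrays. Base differences under probes designed on Columbia, or genes missing from Ws, may add to the pattern. The share lower was 86.2% of the 29 probe sets called at 8-fold or more after median scaling (exact 95% interval 68.3 to 96.1) and 71.4% of the 357 at 2 to 4-fold (66.4 to 76.1), and these intervals overlap even with probe sets counted as independent, which makes them too narrow, so the test decided nothing. Runs of neighbouring loci stay open too: 8 neighbouring pairs were both called lower against 7 at the 95th percentile of 10000 shuffles, but only 48.0% of the calls lower in Ws could be placed on a chromosome, which makes that check void, and a difference in expression between the ecotypes remains an untested explanation.

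More probe sets were 2-fold higher in fnr1 in Columbia than in Ws. The lower level of the wild type Columbia array is argued against as the whole source, since 3 scalings that remove it left more in Columbia: 112 against 41 with quantile normalization, 104 against 38 with median scaling and 106 against 42 with cyclic loess. Array noise stays open: Columbia also had more probe sets 2-fold lower after quantile normalization, 28 against 13 (68.3% in Columbia), and although the 104 higher in Columbia after median scaling had a median of 0.332 in Ws, against -0.095 to 0.047 for random sets matched on mean signal, that does not show what the excess in Columbia is. A chromosome segment of another line carried by the Columbia mutant could not be decided: at most 3 such loci lay within 50 neighbouring tested loci, which was also the 95th percentile of shuffles, but only 32.7% of the set could be placed. A larger response to the mutation in Columbia and a difference in RNA quality (an older actin control had a 3' to 5' ratio of 30.3 in fnr1 and 15.2 in wild type Columbia, but the other actin control had 2.58 and 2.78, GAPDH 0.82 and 0.90, and the older GAPDH control 1.48 in both) are hypotheses that 1 array per group leaves untested.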
